A study of Mus musculus with 12 samples.

How the data were processed

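Poly(A)-selected RNA of C2C12 cells, an established line of mouse myoblasts, was sequenced on a Singular G4 instrument with paired reads of 50 bases after 14 PCR cycles, per the labels' protocols. The labels give 6 libraries of wild-type cells (WT) and 6 of a line that carries a genetically encoded calcium indicator (RGECO). Both lines grew on a hydrogel of methacrylated gelatin. They were taken through 14 days of differentiation in medium with 10% horse serum, the growth factor IGF-1 at 50 ng per ml and aminocaproic acid at 1 mg per ml, per the labels.

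The authors deposited a table of estimated counts per gene and a table of TPM (transcripts per 1000000) per gene, both merged over samples from Salmon, per the file headers and names. The deposited estimated counts are not normalised and need not be whole. The deposited TPM values are corrected for transcript length and scaled by the authors so that every library sums to 1000000. Per the submitters' processing notes, the tools were BWA 0.7.12-r1039, bedtools 2.25.0, STAR and Salmon, and the builds mm10, hg19 and GRCm39. The role of each tool and build, the annotation release, the Salmon version and the strand setting are not given in the sources used here. Because strand is not stated, reads of a gene and of an antisense partner cannot be told apart. Some genes with close copies are marked as uncertain where they are named, and other genes may share reads too.

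The count table held 78298 genes. The library of RGECO replicate 4 held 825 counts in 252 genes, against 5881622 to 11926220 counts in the other 11 libraries. The design fixed before the data were examined used all 12 libraries. RGECO replicate 4 was left out of the main fits on its total alone, with a minimum of 1000000 counts set before any test was run, so the main values compare 6 WT with 5 RGECO libraries and depart from that design in this point. The fits with all 12 libraries, as first designed, were computed as an alternative. Every column matched a sample of the labels. Over the 25 pairs of libraries within a line, the smallest chi-square per gene was 7.69, so no pair was treated as the same library. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

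Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and the line was tested with the quasi-likelihood F test with robust dispersions (glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment over the 13318 genes kept and a threshold of adjusted p 0.05. Standard errors and 95% intervals of log2 fold changes were taken from the F statistic and its degrees of freedom. The common coefficient of variation between libraries of a line was 25.2%. Counts per 1000000 counts of a library (CPM) were scaled by TMM. The floor of 3 counts is 0.252 to 0.510 CPM per library, and floors and counting intervals cover counting error only. In counts simulated for these 13318 genes from the real means, dispersions and library totals, the test recovered 55.0% of genes changed 2-fold and 92% of genes changed 4-fold, each with the right sign, 4.55% of the calls were genes left unchanged, and 0 genes were called when none was changed. A block of 500 genes lowered by 0.25 in the same simulation came out at -0.24. The simulation drew genes independently and so lacks any gradient shared across genes. A split of the real libraries that mixed the lines called 980 genes, so the simulated error rates may be too low for these data.

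Gene lists, 36 in all, were fixed before the data were examined. They cover contractile, calcium, junction, matrix, growth, stress and metabolic genes and markers of other cell types, and 35 lists had at least 3 measured members. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 35 lists. Camera with an estimated correlation and fry were run beside it. Myosin heavy chain shares were computed per library as percent of the summed TPM of 6 genes. These shares, the mitochondrial share of counts and the number of genes with a count were compared by two-sided exact permutation tests over all 462 assignments of the 11 libraries, for which the smallest possible p is 0.00216. The spread between libraries of a line was the mean distance between log2 CPM profiles (prior count 2) over the 500 genes most variable within lines. Its difference between the lines was tested by permuting the libraries after each line's mean was subtracted. Values centred in this way are not fully exchangeable between lines, so the p of this test is approximate and not exact.

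Genes named in the text follow a rule fixed before the data were examined. Its first part takes, among genes past adjusted p 0.05 with a mean log2 CPM of at least 4 and no overlap between the lines, without predicted genes, the 10 with the highest and the 10 with the lowest log2 fold change. Its second part takes up to 4 members with the smallest adjusted p from each list described, and its last part is a fixed set of genes given whatever their values, of which 1 is not reported here. How many of these list members are named, and which lists are described, was settled after the values and the fits without single libraries had been seen, and members that depend on single libraries were named less often: of 98 called genes that the rule takes over all lists 75 are named, and of the 23 that are not named 17 lost their call without some single library and 1 kept it under every alternative. Genes chosen after their values were seen are marked in the text. Gene identifiers are those of the count table. Chromosome, coordinates and gene type come from GENCODE M21 on GRCm38, matched by Ensembl identifier for 12953 of the 13318 tested genes, and not from the annotation used for counting. Transcripts of that release were compared with BLAST 2.17.0.

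Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 6 libraries, unrounded counts, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), a threshold of 0.01, the replicate number as a block, and each library left out in turn. The mitochondrial share, the share of the nuclear RNA Malat1 or 1 surrogate variable from sva 3.50.0 as a covariate, and leaving out chromosome 13 were added after the data were seen. The fit with all 12 libraries follows the design fixed beforehand and became an alternative once RGECO replicate 4 was left out.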

Results

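Gene expression was measured in muscle tissues made from C2C12 mouse myoblasts, with 6 libraries of wild-type cells and 6 of the RGECO line, as part of work on hydrogel platforms for neuromuscular tissue. The comparison asks how far a line with a calcium indicator resembles its parent after 14 days of differentiation. The WT libraries held 9370322 to 11744314 counts and 18912 to 20176 genes with a count. Of the RGECO libraries, 5 held 5881622 to 11926220 counts and 15584 to 19410 genes with a count. RGECO replicate 4 held 825 counts and is left out of the values below unless it or all 12 libraries are named. Calls gained or lost with all 12 libraries may stem from this near-empty library rather than from the lines. Genes with a count numbered 19700 ± 491 (SD, n = 6) in WT and 17908 ± 1562 (SD, n = 5) in RGECO (exact permutation p = 0.0130). This number depends on depth, which was not adjusted for. The libraries with the fewest counts, RGECO replicates 5 and 1, had 15584 and 17229 such genes. RGECO replicates 2 and 3 had 19410 and 19165, inside the WT range, while RGECO replicate 6, with 11926220 counts, had 18152. Median Spearman correlations over tested genes were 0.975 within WT, 0.974 within RGECO and 0.964 between the lines. RGECO replicate 5 had the fewest counts of these 11 libraries and stood farthest from the others on the first dimension of a multidimensional scaling.

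Among the genes that changed most, Cxcl12 and Col1a1 were lower and Lpl was higher in the RGECO tissues. Cxcl12 (ENSMUSG00000061353, chromosome 6: 117168535 to 117181367, GRCm38), a chemokine, fell from 55.2 ± 2.31 CPM (SD, n = 6) in WT to 9.74 ± 4.04 CPM (SD, n = 5) in RGECO, a log2 fold change of -2.52 ± 0.21 (SE, adjusted p = 8.89e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Lpl (ENSMUSG00000015568, chromosome 8: 68880491 to 68907448, GRCm38), the lipase that frees fatty acids from circulating triglycerides, rose from 18.3 ± 4.56 CPM (SD, n = 6) to 97.3 ± 23.2 CPM (SD, n = 5), a log2 fold change of 2.42 ± 0.19 (SE, adjusted p = 4.77e-06). Col1a1, the main chain of type I collagen, fell from 2032 ± 461 CPM (SD, n = 6) to 512 ± 190 CPM (SD, n = 5), a log2 fold change of -1.98 ± 0.23 (SE, adjusted p = 7.18e-05; 0.0511 with all 12 libraries).

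The other genes with the lowest log2 fold changes were the collagen receptor subunit Itga11 at -2.17, the complement proteases C1ra at -2.09 and C1s1 at -2.00, the LIM-domain gene Lmcd1 at -2.07, the cartilage matrix gene Cilp at -1.99, the immediate-early transcription factor Egr3 at -1.86, the hyaluronan synthase Has2 at -1.80 and complement C3 at -1.74. The other genes with the highest were Prl2c3 at 2.17, the matricellular gene Ccn3 at 2.15, the glucosidase Mgam at 1.56, the phospholipase Pla1a at 1.52, Prrg4 at 1.52, Mal at 1.50, the polarity gene Pard3b at 1.45, Bglap2 at 1.36 and the thioredoxin inhibitor Txnip at 1.29. In each of these 20 genes no library of one line reached the range of the other, as the rule for naming them requires. C1ra, C1s1, Prl2c3 and Bglap2 have close paralogs, so their values are uncertain. Txnip lost its call with all 12 libraries (log2 fold change 1.08, adjusted p = 0.304).

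**Figure D1:**
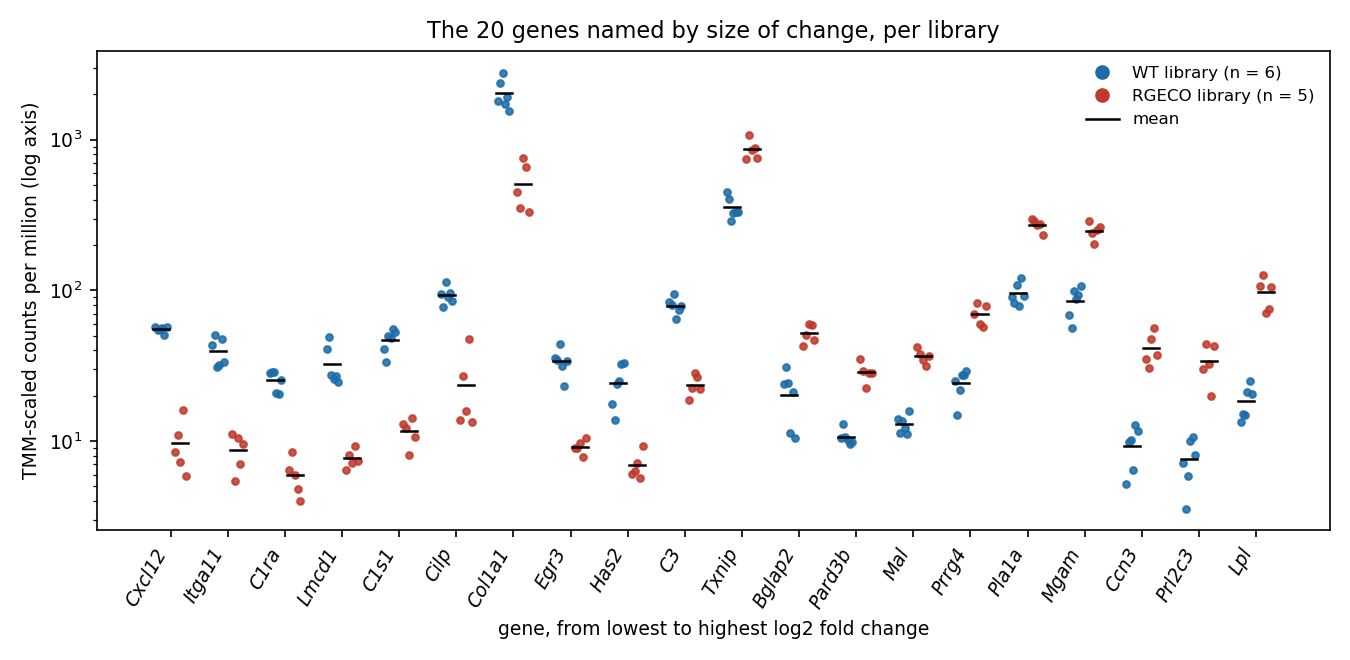
TMM-scaled CPM (log axis) of the 20 genes named by size of change, one point per library (6 WT, 5 RGECO), with a bar at each mean, ordered from lowest to highest log2 fold change. Cxcl12 lies at 50.9 to 57.1 CPM in WT and 5.84 to 16.1 CPM in RGECO.

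Across the 13318 genes tested, 1112 passed adjusted p 0.05, of which 456 were higher and 656 lower in RGECO. Of these, 411 changed beyond 2-fold, with 130 higher and 281 lower. For 9861 genes, 74.0% of those tested, the 95% interval of the fold change lay inside 2-fold in either direction, and 2794 genes neither passed nor had such an interval. The median log2 fold change was -0.01. The fit on log2(TPM + 1) called 556 genes, of which 324 were higher and 232 lower. With 0.1 added in place of 1 it called 529 genes, and with 1 added and no filter 258. The fit with all 12 libraries called 820 genes, of which 237 were higher and 583 lower. With the mitochondrial share of counts as a covariate, chosen after the data were seen, 3133 genes passed, 1614 higher and 1519 lower. With the Malat1 share, chosen likewise, 2771 passed, 1395 higher and 1376 lower.

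The indicator's own sequence is not analysed here. Indicators of the R-GECO family join calmodulin and a peptide of myosin light chain kinase to a red fluorescent protein, so counts of Calm2, Calm3 and the kinase genes Mylk and Mylk2 serve as the nearest check of the labels. Calm2 (ENSMUSG00000036438, chromosome 17: 87433412 to 87446935, GRCm38) was 87.3 ± 13.8 CPM (SD, n = 6) in WT and 120 ± 17.7 CPM (SD, n = 5) in RGECO, a log2 fold change of 0.47 ± 0.13 (SE, adjusted p = 0.0396). The log2 fold changes of Calm3 at 0.27, Mylk at -0.16 and Mylk2 at -0.57 did not pass (adjusted p = 0.342, 0.504 and 0.102), though Mylk2 passed at -0.76 without RGECO replicate 3 (adjusted p = 0.0296). The Calm2 call was lost without WT replicate 1, 2 or 3 and without RGECO replicate 1, 2, 5 or 6, each taken alone (adjusted p = 0.0819, 0.0543, 0.0704, 0.0520, 0.0730, 0.0996 and 0.0569), and with all 12 libraries (log2 fold change 0.41, adjusted p = 0.431). The change of Calm2 was larger on log2(TPM + 1), at 1.27 (adjusted p = 5.31e-04). TPM is corrected for transcript length and counts are not, so this value need not mean a larger change in Calm2 RNA.

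Pseudogenes that resemble Calm2 were counted in the RGECO libraries and almost absent from WT. They were chosen after their values were seen. Gm7308 (ENSMUSG00000081113, chromosome 6: 127282063 to 127282509, GRCm38) had 4 counts over the 6 WT libraries and 3532 over the 5 RGECO libraries, a CPM ratio of 1143 (95% counting interval 449 to 4223). Gm15720 (chromosome 6: 146463326 to 146463607, GRCm38) had 0 and 1240 counts, at least 538-fold higher in RGECO against a floor of 3 counts over the WT group. Gm14480 (chromosome X: 10696932 to 10697364, GRCm38) had 0 and 423 counts, at least 184-fold higher on the same floor. Their annotated transcripts aligned to Calm2 with 96.9%, 98.2% and 91.1% identity in that order, so the genomic source of these counts is uncertain. Together the 3 genes had counts equal to 69.5% to 179% of the Calm2 counts in RGECO libraries, or to 102% without RGECO replicate 5, and 0.0753% of them over the WT libraries.

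**Figure D2:**
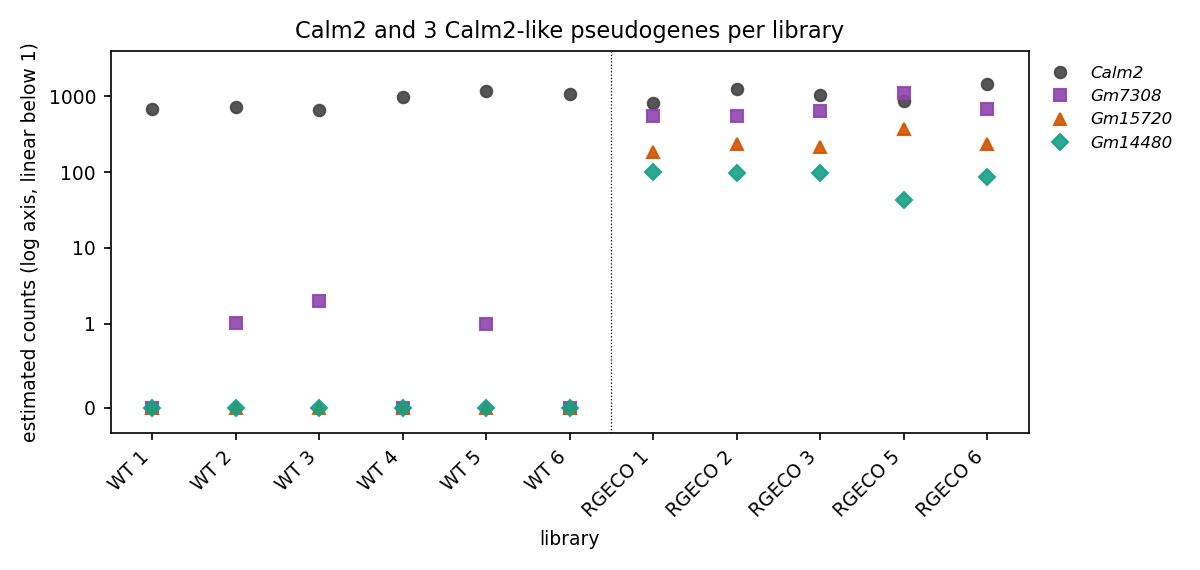
Estimated counts (log axis, linear below 1) of Calm2 and of 3 processed pseudogenes that resemble it, per library, with 6 WT libraries left of the dotted line and 5 RGECO libraries right of it. Gm7308 reaches at most 2 counts in a WT library and at least 543 in an RGECO library.

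Both lines expressed the myosin heavy chain genes of developing and adult fibres, in different proportions. Myh3, the embryonic chain, made up 27.9% ± 1.57 (SD, n = 6) of the summed TPM of 6 myosin heavy chain genes in WT and 43.0% ± 3.85 (SD, n = 5) in RGECO (exact permutation p = 0.00216, the smallest 462 assignments can give; adjusted p = 0.00649 over the 6 genes). Myh8, the neonatal chain, made up 14.6% ± 1.33 (SD, n = 6) and 7.38% ± 1.28 (SD, n = 5; exact permutation adjusted p = 0.00649). Myh7, the slow chain, made up 26.3% ± 1.66 (SD, n = 6) and 18.9% ± 3.78 (SD, n = 5; exact permutation adjusted p = 0.00866). The adult fast chains did not pass, with 21.7% and 22.7% for Myh1, 0.701% and 0.540% for Myh2, and 8.67% and 7.45% for Myh4 in WT and RGECO (exact permutation adjusted p = 0.212, 0.177 and 0.177), and the Myh1 difference turned to -0.0778 percentage points on estimated counts (exact permutation adjusted p = 0.942). The summed TPM of the 6 genes was 1080 ± 133 (SD, n = 6) in WT and 1092 ± 99.8 (SD, n = 5) in RGECO (exact permutation p = 0.870). Shares of 1 sum are not independent, so a rise in Myh3 lowers the others. In WT replicate 1 the estimated counts of these 6 genes were not whole, as 6537.84 for Myh8. Reads may be shared between related myosin genes, and the shares are uncertain to that extent.

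**Figure D3:**
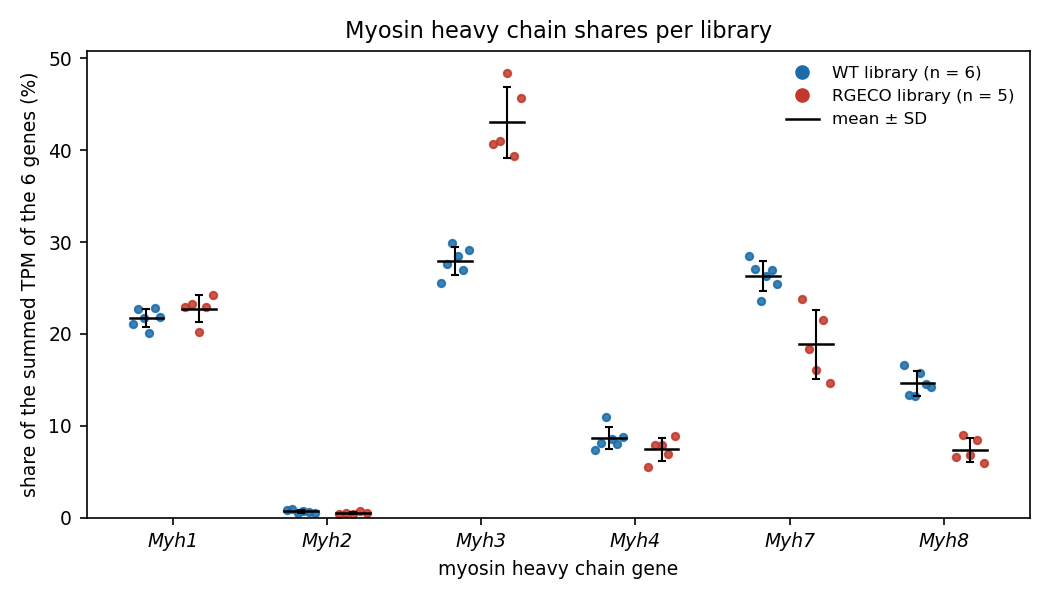
Share of each of 6 myosin heavy chain genes in their summed TPM (%), one point per library (6 WT, 5 RGECO), with mean and SD. The Myh3 points lie at 25.5% to 29.9% in WT and 39.4% to 48.4% in RGECO.

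In the count fit the same genes moved in the same directions, with log2 fold changes of 0.54 ± 0.13 (SE) for Myh3, -1.06 ± 0.15 (SE) for Myh8 and -0.54 ± 0.13 (SE) for Myh7 (adjusted p = 0.0202, 3.83e-04 and 0.0124 by edgeR's quasi-likelihood test). The Myh3 call was lost without RGECO replicate 3 (log2 fold change 0.43, adjusted p = 0.0575), and with all 12 libraries those of Myh3, Myh8 and Myh7 were lost (adjusted p = 0.962, 0.136 and 0.657). Of 11 measured developmental myofibre genes 1 rose and 2 fell, Igf2 among them at -0.52 (adjusted p = 0.00963), with the same numbers adjusted over the list alone. Of 28 core sarcomere genes 1 rose, Lmod2 at 0.57, and 3 fell, led by Myot at -0.65 and Actn2 at -0.66, and the numbers adjusted over the list alone were the same. Of 18 fast-fibre genes 0 rose and 3 fell, led by the calcium buffer Pvalb at -1.04, and of 17 slow-fibre genes 1 rose and 1 fell, or 4 and 1 adjusted over the list alone. None of these 4 lists passed camera (adjusted p = 0.685 for developmental, 0.663 for core sarcomere, 0.348 for fast and 0.348 for slow). With all 12 libraries, RGECO replicate 4 at 825 counts included, the developmental, core sarcomere and fast lists passed as lower in RGECO (camera adjusted p = 0.00118, 1.91e-04 and 5.11e-04). With the Malat1 share as a covariate the fast list also passed as lower (camera adjusted p = 0.0142). Acta1, the skeletal actin, differed by 0.22 ± 0.15 (SE), titin (Ttn) by 0.07 ± 0.16 (SE) and the muscle creatine kinase Ckm by -0.35 ± 0.16 (SE), none past the threshold and each with its 95% interval inside 2-fold. Pvalb lost its call without RGECO replicate 6 (log2 fold change -0.93, adjusted p = 0.0505). With all 12 libraries the calls of Igf2, Lmod2 and Actn2 were lost (adjusted p = 0.685, 0.563 and 0.386). Those of Igf2 and Myot were lost on log2(TPM + 1) (adjusted p = 0.244 and 0.0674).

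Genes that set the muscle programme differed in part. Of 14 measured myogenic regulators 2 rose and 4 fell, and 4 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.786). Eya4 fell by 0.65 on the log2 scale (adjusted p = 0.0111) and Myod1, a determination factor, fell by 0.51 (adjusted p = 0.0277), while Myf5 rose by 0.58 (adjusted p = 0.0228). Myog, needed for differentiation, at -0.18 and Pax7, a satellite cell factor, at 0.46 did not pass (adjusted p = 0.596 and 0.0822), though Pax7 passed at 0.55 without WT replicate 2 (adjusted p = 0.0348). The Myod1 call was lost without WT replicate 1, 3 or 5 or RGECO replicate 2, 5 or 6 (adjusted p = 0.0665, 0.0734, 0.0555, 0.0985, 0.0687 and 0.0902), and that of Myf5 without RGECO replicate 1 (adjusted p = 0.0656). Of 17 fusion genes 1 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0807; 0.0323 without WT replicate 3, 0.0432 without RGECO replicate 6 and 0.0356 with 1 surrogate variable, each as higher in RGECO), and the fusion proteins Mymk at 0.22 and Mymx at 0.08 did not pass. Cav3, caveolin of muscle, fell by 0.80 (adjusted p = 0.0143; 0.0518 without RGECO replicate 2). Under the replicate block the calls of Eya4 and Myf5 were lost (adjusted p = 0.0519 and 0.0719). With all 12 libraries those of Myod1 and Myf5 were lost (adjusted p = 0.186 and 0.0796). On log2(TPM + 1) those of Myod1 and Myf5 were lost (adjusted p = 0.144 and 0.0718), and Mymk passed at 0.35 (adjusted p = 0.0427).

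Among 30 excitation-contraction coupling genes 25 had a 95% interval inside 2-fold, and among 22 calcium signalling genes 17 had one. Over all genes tested the share with such an interval was 74.0%, so this trait is not particular to these lists. Ryr1 at 0.21, Cacna1s at 0.11, the calcium pumps Atp2a1 at -0.14 and Atp2a2 at 0.08, and the store protein Casq1 at -0.06 did not pass, and each of these log2 fold changes had its 95% interval inside 2-fold. Of the 30 excitation-contraction coupling genes 0 rose and 3 fell, or 1 and 4 adjusted over the list alone, among them the ryanodine receptor Ryr3 at -0.67 and triadin (Trdn) at -0.77 (adjusted p = 0.00779 and 0.0104; camera adjusted p for the list = 0.995, or 0.00118 as lower with all 12 libraries). Of the 22 calcium signalling genes 2 rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.995). Rcan2, a regulator of calcineurin, rose by 1.29 (adjusted p = 2.41e-04), while the calcineurin-dependent transcription factors Nfatc4 and Nfatc1 fell by 2.17 and 0.91 (adjusted p = 2.50e-04 and 0.00102). Of 22 neuromuscular junction genes 0 rose and 2 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.751). These were Nrg1 at -1.25 (adjusted p = 5.60e-04) and Dok7 at -0.97 (adjusted p = 0.0160; 0.0610 without RGECO replicate 2). The receptor genes Chrna1 at -0.04, Chrnb1 at 0.14, Chrnd at 0.02 and Chrng at -0.04 and the kinase Musk at -0.12 did not pass and had intervals inside 2-fold, whereas the adult subunit Chrne, at 1.2 ± 0.8 CPM in WT, was too low to bound. On log2(TPM + 1) the calls of Ryr3, Trdn, Nrg1 and Dok7 were lost (log2 fold change -0.69, -0.44, -1.24 and -0.83; adjusted p = 0.0776, 0.164, 0.0620 and 0.0549). Nfatc4 was at -1.04 there (adjusted p = 0.0323). Under the replicate block that of Trdn was lost (adjusted p = 0.0580).

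Among the 35 lists tested, 6 passed camera with the preset correlation and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05, and fry passed 9. As many lists passed in 47 of 100 splits of the same libraries, the real split included. Of 33 measured extracellular matrix genes 4 rose and 14 fell, or 5 and 20 adjusted over the list alone, with a median log2 fold change of -0.45 (camera adjusted p = 1.48e-05; adjusted p = 0.469 with an estimated correlation). Besides Col1a1, the collagen chains Col6a1 at -1.59, Col12a1 at -1.33 and Col6a2 at -1.64 fell (adjusted p = 2.13e-05, 2.13e-05 and 8.08e-05). The members that rose, listed after their values were seen, were Loxl2 at 0.86, decorin (Dcn) at 0.96, Lama2 at 0.56 and Fbn1 at 0.42 (adjusted p = 2.44e-04, 0.00193, 0.0244 and 0.0305). The call of Lama2 was lost without WT replicate 1 or RGECO replicate 2 or 3 (adjusted p = 0.0528, 0.0644 and 0.0623), and that of Fbn1 without WT replicate 1, 5 or 6 or RGECO replicate 2, 3 or 5 (adjusted p = 0.0697, 0.0568, 0.0564, 0.0921, 0.0527 and 0.0738). Of 16 matrix remodelling genes 4 rose and 5 fell, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.571), with the gelatinase Mmp2 at -1.12, Adamts2 at -1.06 and Serpinf1 at -0.68 lower and Adamts1 at 0.46 higher. Of 10 markers of fibroblast-adipogenic cells 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.758), with the growth factor receptor Pdgfrb at -1.59 and Ly6a at 0.96. With all 12 libraries the calls of Dcn, Lama2, Fbn1, Mmp2, Serpinf1, Adamts1 and Ly6a were lost (adjusted p = 0.165, 0.605, 0.907, 0.227, 0.320, 0.625 and 0.473). The calls of Lama2, Fbn1 and Adamts2 were lost on log2(TPM + 1) (adjusted p = 0.0664, 0.0771 and 0.110, with Adamts2 at -0.59). Under the replicate block that of Fbn1 was lost (adjusted p = 0.0619).

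Of 31 cell-cycle genes 1 rose and 6 fell, or 1 and 11 adjusted over the list alone, with a median log2 fold change of -0.43 (camera adjusted p = 6.03e-04; adjusted p = 0.543 with an estimated correlation). Cyclin B1 (Ccnb1) at -0.84 and the centromere histone Cenpa at -0.64 fell and cyclin E1 (Ccne1) at 0.72 rose (adjusted p = 0.00659, 0.0158 and 0.0185), and Mki67 at -0.52 did not pass (adjusted p = 0.152; 0.0414 without WT replicate 1). Of 21 immediate-early genes 1 rose and 6 fell, or 2 and 12 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.0104; adjusted p = 0.876 with an estimated correlation, and 0.0550 without WT replicate 2). Besides Egr3, the nuclear receptor Nr4a3 at -1.57 and Egr2 at -1.07 fell, and the phosphatase gene Dusp1 rose by 0.85 (adjusted p = 0.00180, 0.00218 and 8.82e-05). Under the replicate block the calls of Ccnb1 and Ccne1 were lost (adjusted p = 0.0519 and 0.0641). That of Cenpa was lost with all 12 libraries and on log2(TPM + 1) (adjusted p = 0.0583 and 0.226). Nr4a3 was at -1.01 on log2(TPM + 1) (adjusted p = 0.0249).

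Of 18 p53 target genes 2 rose and 0 fell, or 5 and 0 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 5.98e-05; adjusted p = 0.0908 with an estimated correlation, and 0.389 with all 12 libraries). These were Btg2 at 0.67 and Zmat3 at 0.45 (adjusted p = 8.52e-04 and 0.0115). Of 12 fixed adipocyte genes only 5 were measured. Of these 4 rose and 0 fell, or 4 and 1 adjusted over the list alone, with a median of 0.73 (camera adjusted p = 0.00159; adjusted p = 0.0908 with an estimated correlation). Besides Lpl they were the lipid droplet gene Plin4 at 1.05, the carbonic anhydrase Car3 at 0.70 and the receptor Pparg at 0.73 (adjusted p = 0.00364, 0.00462 and 0.00917). Of 18 fixed neuronal genes only 7 were measured. Of these 4 rose and 0 fell, or 5 and 0 adjusted over the list alone, with a median of 0.75 (camera adjusted p = 0.00267; adjusted p = 0.167 with an estimated correlation). They were the neurofilament gene Nefl at 1.27, Tubb3 at 0.78, Gap43 at 0.84 and Map2 at 0.75 (adjusted p = 0.00162, 0.0255, 0.0298 and 0.0326). The Tubb3 call was lost without WT replicate 1 or 4 or RGECO replicate 1 or 5 (adjusted p = 0.0595, 0.0523, 0.0760 and 0.0692). That of Gap43 was lost without WT replicate 1 or 5 or RGECO replicate 1, 5 or 6 (adjusted p = 0.0558, 0.0512, 0.0651, 0.0587 and 0.0602). That of Map2 was lost without WT replicate 1 or 5 or RGECO replicate 2, 3 or 5 (adjusted p = 0.0596, 0.0561, 0.0801, 0.0575 and 0.0654). With all 12 libraries the calls of Btg2, Zmat3, Car3 and Gap43 were lost (adjusted p = 0.486, 0.651, 0.648 and 0.0848). Zmat3, Pparg and Gap43 lost theirs on log2(TPM + 1) (adjusted p = 0.0520, 0.0502 and 0.0814). Under the replicate block those of Zmat3 and Gap43 were lost (adjusted p = 0.0502 and 0.115).

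**Figure D4:**
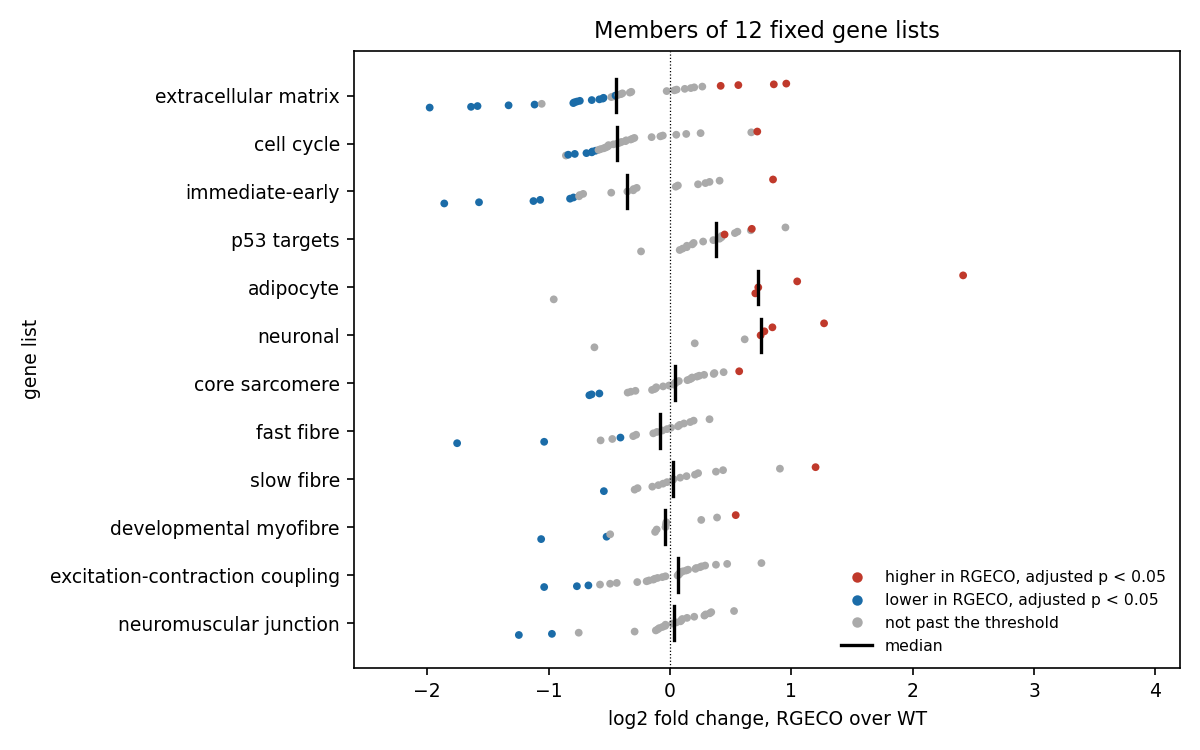
Log2 fold change (RGECO over WT) of each measured member of 12 fixed gene lists, one point per gene, coloured by its call, with a bar at each list's median. The medians of extracellular matrix, cell cycle and immediate-early genes lie at -0.45, -0.43 and -0.35, and those of p53, adipocyte and neuronal genes at 0.38, 0.73 and 0.75.

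Mitochondrial transcripts and the likeness of replicate tissues were compared as measures of each library. Mitochondrially encoded genes took 0.986% ± 0.591 (SD, n = 6) of counts in WT and 0.698% ± 0.389 (SD, n = 5) in RGECO, a difference within the spread between libraries (exact permutation p = 0.372). Within lines the share ran from 0.204% in WT replicate 2 to 1.68% in WT replicate 4, and from 0.298% in RGECO replicate 5 to 1.33% in RGECO replicate 6. Of 12 measured mitochondrially encoded genes 0 passed edgeR's test, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.0861). As a list they passed as lower in RGECO without WT replicate 2 or 3 or RGECO replicate 6 (camera adjusted p = 3.35e-04, 0.0323 and 0.00195), with all 12 libraries (0.0206) and with 1 surrogate variable as a covariate (0.00107). Of 27 oxidative phosphorylation genes likewise 0 passed and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.564). The mean distance between libraries of a line was 2.03 in WT and 2.50 in RGECO on the log2 CPM scale (approximate permutation p = 0.0844 for the difference of 0.475). That difference was 0.109 over all genes tested (approximate permutation p = 0.286). It was 0.202 without RGECO replicate 5. It passed the threshold at 0.640, 0.619 and 0.607 without WT replicate 2, RGECO replicate 2 or RGECO replicate 3 (approximate permutation p = 0.0397, 0.00952 and 0.0143).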

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

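In 236 groups of values behind the results named here, 12 values lay far from the others of their line, and chance flags about 1 in 20 groups, or 11.8. They fell in 7 of the 11 libraries, with 4 in RGECO replicate 5. Its Gm7308 was 193 CPM against 53.7 to 72.2 in the other RGECO libraries, its Gm15720 was 64.2 CPM against 19.3 to 24.1, its Eya4 was 38.6 CPM against 56.1 to 57.2, and its Myh2 share of myosin heavy chain TPM was 0.762% against 0.465% to 0.521%. RGECO replicate 1 was highest of its line in Dusp1 at 206 CPM against 171 to 176, and in Myf5 at 33.9 CPM against 25.9 to 27.7. RGECO replicate 2 was highest of its line in Serpinf1 at 327 CPM against 263 to 279. WT replicate 1 was highest of WT in Btg2 at 237 CPM against 180 to 200.3, and lowest in Gap43 at 2.33 CPM against 3.73 to 4.25. WT replicate 2 was highest of WT in Pard3b at 12.9 CPM against 9.54 to 10.7, WT replicate 3 in Chrne at 2.80 CPM against 0.415 to 1.23, and WT replicate 5 in total counts at 11744314 against 9370322 to 9970556.

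The Calm2-like pseudogenes were counted in all 5 RGECO libraries, and the tests of this pattern were chosen after the counts were seen. Among 51498 genes with a GENCODE M21 transcript, 8 resembled calmodulin at 85% identity over 200 bases, and 5 had at least 10 counts in every RGECO library and at most 3 in every WT library. These 5 include the 3 pseudogenes, which prompted the search and so cannot test it, and of the other 2 genes 0 resembled calmodulin, too few to decide whether reads of the indicator's calmodulin part were assigned to copies of Calm2. A spill-over of the cells' own Calm2 reads is argued against by WT, where the pseudogene counts were 0.0753% of the Calm2 counts with an upper 95% limit of 0.193%, against at least 69.5% in an RGECO library. The ratio of Gm14480 to Gm7308 ranged 4.79-fold over the RGECO libraries, against 1.29-fold for Gm15720, but 1.43-fold without RGECO replicate 5, where it was 0.0379 against 0.127 to 0.181, so whether these 2 come from 1 source in a fixed ratio stays open. A candidate explanation for the 3 pseudogenes is that reads of the indicator's calmodulin part were assigned to these copies, and it stays open beside transcription from the pseudogenes themselves, since reads are not analysed here.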

How the results depend on the processing

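Alternatives chosen after the data were seen were the 3 covariates and leaving out chromosome 13. The fit with all 12 libraries, the design fixed beforehand, became an alternative once RGECO replicate 4 was left out. Of the 98 called genes that the fixed rule takes over all lists, whether named in the text or not, 35 kept their call under every alternative run on single genes, 28 lost it without some single library, 35 with all 12 libraries, 34 with limma on log2(TPM + 1) and 20 under the replicate block, and 0 changed direction. Of the 75 of them named in the text 34 kept their call under every alternative, but these were chosen with that stability in view. The 1112 genes past adjusted p 0.05 became 542 at a threshold of 0.01. On TPM they became 556 with 1 added before the log, of which 324 were higher and 232 lower and 466 were shared with the main fit, 529 with 0.1 added and 258 with no filter, and the 411 beyond 2-fold became 226, 251 and 161 in that order. With the mitochondrial share as a covariate 3133 genes passed, with the Malat1 share 2771 and with 1 surrogate variable 2855, holding 1110, 1104 and 1111 of the 1112. RLE (1112), upper-quartile scaling (1124), limma-voom (1164), no filter (1071), DESeq2 (1595) and all 12 libraries (820) stayed within 1.5 times, and 662 of those 820 were shared. Without single libraries the count ranged from 785 to 1140, that beyond 2-fold from 358 to 426, genes with an interval inside 2-fold from 9415 to 9879 and lists called from 6 to 9.

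The 6 lists called became 0 with an estimated correlation, where the adjusted p was 0.469 for extracellular matrix, 0.543 for cell cycle, 0.876 for immediate-early, 0.0908 for p53 targets, 0.0908 for adipocyte and 0.167 for neuronal genes. Fry gained fusion genes as higher (0.0209) and reserve cell, imprinted and osteo-chondrogenic genes as lower in RGECO (0.0292, 0.0292 and 0.0329), and lost immediate-early genes (0.154), whose adjusted p ranged from 8.30e-04 to 0.0550 without single libraries. With the mitochondrial share, the Malat1 share or the surrogate variable as a covariate 7, 8 and 8 lists passed. The lists gained were ribosomal protein genes, lower with either share (adjusted p = 0.00958 and 8.11e-05), fast-fibre genes, lower with the Malat1 share (0.0142), and mitochondrially encoded genes, lower, and fusion genes, higher, with the surrogate variable (0.00107 and 0.0356). The replicate block gained ribosomal protein genes as lower (0.0182) and cholesterol synthesis genes as higher (0.0424). Among fits without 1 library, mitochondrially encoded genes passed as lower in 3 and fusion genes as higher in 2, ribosomal protein genes as lower without WT replicate 6 or RGECO replicate 2 (0.0152 and 0.0212), and cholesterol synthesis genes as higher without RGECO replicate 3 or 6 (0.0389 and 0.0432). With all 12 libraries 15 lists passed and p53 targets did not (0.389). The lists gained there were all lower in RGECO: excitation-contraction coupling, developmental myofibre, fast fibre, imprinted, mitochondrially encoded, atrophy, smooth muscle (0.00647) and ribosomal protein genes (4.53e-05), and core sarcomere and hypoxia and glycolysis, which turned direction (1.91e-04 and 6.62e-05). RGECO replicate 4 brings 336 counts in the tested genes to that fit, so lists gained there cannot be read as differences between the lines. Calm2 was 0.41 with all 12 libraries (adjusted p = 0.431), 0.38 to 0.53 without single libraries and 1.27 on log2(TPM + 1) (adjusted p = 5.31e-04), and Mylk2 ranged from -0.76 to -0.48, past adjusted p 0.05 over all genes without RGECO replicate 3 (adjusted p = 0.0296). The Myh1 share difference ranged from 0.627 to 1.62 percentage points without single libraries and passed without RGECO replicate 3, but turned to -0.0778 on estimated counts in place of TPM (exact permutation adjusted p = 0.942). The Myh4 share difference of -1.22 became -1.88 there (exact permutation adjusted p = 0.0552). The difference in spread was 0.109 over all genes tested, 0.326 over 2000 genes and 0.412 on log2(TPM + 1) (p = 0.286, 0.113 and 0.0303 by approximate permutation), and 0.202 to 0.640 without single libraries. Myosin shares could not be computed for RGECO replicate 4, whose 6 genes were listed at 0, and the spread was not run with it.

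The replicate numbers did not pair the samples, with correlations of deviations from the line means of 0.03, -0.25, 0.02, -0.33 and 0.64 for numbers 1, 2, 3, 5 and 6, and of these 5 RGECO libraries only replicate 6 correlated best with the WT library of its number. With the replicate block 777 genes passed, 349 of them beyond 2-fold. Sign flips over 5 pairs cannot give a p under 0.0625, and the paired differences were 15.2 percentage points for Myh3, -7.45 for Myh7 and -7.02 for Myh8 (exact adjusted p = 0.125 each). Depth limits genes near the floor of 3 counts, such as Chrne.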

Other observations

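The tests on chromosome 13 without 1 library or with the mitochondrial share, those with the Malat1 share and on matrix-producing cells, Tbx20 and the choice of chromosome 13 itself came after the data were seen. The metallothioneins Mt1 and Mt2, metal-binding genes of the atrophy list, fell by 1.27 and 1.46 on the log2 scale (adjusted p = 0.00161 and 2.47e-04 by edgeR's quasi-likelihood test), with Mt2 at 172 ± 53.7 CPM (SD, n = 6) in WT and 61.9 ± 9.76 CPM (SD, n = 5) in RGECO. Of the 16 genes of that list 0 rose and 2 fell, or 0 and 3 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.906; 0.0467 as lower with all 12 libraries). Among 10 antigen presentation genes the peptide transporter Tap2 fell by 1.65 while B2m rose by 0.64 (adjusted p = 6.88e-04 and 0.0278; list adjusted p = 0.521), and adjusted over the list alone 4 members rose and 2 fell. The B2m call was lost without WT replicate 3 or RGECO replicate 1, 2 or 6 (adjusted p = 0.0571, 0.0616, 0.0787 and 0.0585). Of 23 genes of the unfolded protein and stress response 1 rose and 2 fell, with Ddit3 higher by 0.94 and Atf4 and Herpud1 at -0.45 and -0.70 (adjusted p = 0.00785, 0.00456 and 0.00670; list adjusted p = 0.486). Of 18 heat shock genes the small heat shock gene Hspb1 rose by 0.70 and the co-chaperone Dnajb1 fell by 0.87 (adjusted p = 0.00271 and 0.0146; list adjusted p = 0.348). On log2(TPM + 1) the calls of Tap2, B2m and Atf4 were lost (log2 fold change of Tap2 -0.78; adjusted p = 0.0716, 0.0849 and 0.0771), with all 12 libraries those of B2m, Atf4, Herpud1 and Hspb1 (adjusted p = 0.740, 0.622, 0.337 and 0.836), and under the replicate block that of B2m (adjusted p = 0.0585).

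Tbx20, a T-box transcription factor known from heart development, had 3 counts over the 6 WT libraries and 247 over the 5 RGECO libraries, a CPM ratio of 107 (95% counting interval 36.3 to 524). It stood at 5.13 ± 1.79 CPM (SD, n = 5) in RGECO. Mest, an imprinted gene, was at -1.90 (adjusted p = 0.00246), or -1.03 on log2(TPM + 1), where its call was lost (adjusted p = 0.0849), and of 15 measured imprinted genes 0 rose and 4 fell, or 1 and 7 adjusted over the list alone (list adjusted p = 0.178; 0.00164 as lower with all 12 libraries).

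Genes of chromosome 13 were lower in RGECO, with a median log2 fold change of -0.25 over 514 genes relative to other genes, of which 77.6% lay below the median of the others (camera adjusted p = 1.17e-06 over 20 chromosomes; adjusted p = 0.219 with an estimated correlation). GC content and transcript length are argued against by a loess fit on both, after which the median was -0.246. A single region is argued against by the 6 bins of 20 Mb, whose medians ran from -0.34 to -0.13. A single RGECO library is argued against by a median of -0.23 or lower when each was left out in turn. With the mitochondrial share as a covariate the median was -0.191 ± 0.0348 (SE over genes). That lies beyond the bound of -0.15, set after the data were seen, by little more than this SE. Within WT the median ran from -0.23 in replicate 2, with the lowest mitochondrial share, to 0.15 in replicate 4, with the highest. A gradient in the mitochondrial share therefore stays open as a cause. With the Malat1 share as a covariate the median was -0.164 ± 0.0367 (SE over genes), too near the bound of -0.15 set for this test, so a gradient in that share stays open as a cause. The test without single RGECO libraries replaced an earlier one, that all RGECO libraries lie below all WT libraries, which was not met. Fewer copies in the whole RGECO line stay open. All 6 bins lay below 0 and 5 of the 6 WT libraries lay above every RGECO library. However, 2 of the 5 RGECO libraries, at -0.19 and -0.16, lay above WT replicate 2 at -0.23. This overlap met the condition named beforehand as evidence against fewer copies. It rests on 1 WT library and is smaller than the WT SD of 0.151, a margin not named beforehand, so it does not decide. The exact permutation p between the lines was 0.0173, not adjusted over the 20 chromosomes among which this one was chosen. A chromosome median as far from the other genes came up in 2 of 100 splits, the real one at 0.246 included, and the other, at 0.252, put WT replicate 2 with the RGECO libraries. A difference in chromosome 13 in part of the cells of either line may remain and was not tested, and without chromosome 13 the number of genes past the threshold was 1034.

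The lower RNA of matrix genes was set against RNA quality and cell makeup. With the mitochondrial share as a covariate the median of the 33 genes was -0.50 (adjusted p = 1.68e-06), and with the Malat1 share it was -0.52 (adjusted p = 5.04e-06), and these medians argue against a gradient in either share common to both lines as the whole cause. These p come from the preset correlation, and without a covariate the list did not pass with an estimated correlation (adjusted p = 0.469). A lower share of matrix-producing cells stays open. While 14 members fell, 4 rose, Loxl2, Dcn, Lama2 and Fbn1, and Pdgfrb and Ly6a moved in opposite directions. The bound on risers was set after the values were seen, and Lama2 and Fbn1 lost their calls without some single libraries, so these values do not decide. A change within matrix-producing cells, as from clonal selection of the indicator line, stays open and was not tested.

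Of the 462 splits of the 11 libraries 100 were drawn, the real one included. Among these, 1 gave as many as 1112 genes past the threshold, and the highest other gave 980. Likewise 1 gave as many as 411 beyond 2-fold, and the highest other gave 104. A chance assignment of these libraries to the lines is thus argued against for both counts. The labels do not say that replicates came from separate cultures, so these splits cannot exclude chance differences between single cultures of the lines. For genes with an interval inside 2-fold, 4 splits, the real one included, gave as few as 9861, a share under the bound set beforehand. The lowest other split, which mixed the lines, gave 9689, fewer than the real one. Chance is therefore not firmly excluded there. For the 6 lists called, 47 splits gave as many and the highest other gave 15, so chance cannot be excluded. Of the other splits 93 called 0 genes with edgeR. The split with 980 set WT replicates 4, 5 and 6 and RGECO replicates 1 and 6 against the rest, which points to a structure shared by both lines: these WT libraries and RGECO replicate 6 had the highest mitochondrial shares, at 1.16% to 1.68% of counts, and RGECO replicate 1 had 0.509%. The Malat1 share parted the 2 sides of that split without overlap, at 0.633% to 0.898% against 0.156% to 0.566%.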
